A study of Mus musculus with 8 samples.

How the data were processed

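RNA from 8 dorsomedial hypothalamus samples of mice, 4 per hairpin, was isolated with a kit for small amounts of tissue and made into libraries with a SMARTer kit, per the labels' protocols. The authors' deposited gene tables hold, per the file headers, the length, effective length, TPM and estimated count of reads of 55487 Ensembl gene identifiers in each library. The submitters' processing notes name bcl2fastq, DRAGEN, edgeR and limma without versions or roles. The aligner settings, genome build and annotation are not given in the sources used here. The expected counts deposited by the authors need not be whole (up to 10.1% of genes in a library had a fractional value), and they were rounded to whole numbers. The deposited TPM values, scaled by the authors to gene length and library, were used in an alternative. The deposited effective length of each gene, per the file headers, served as an offset in another. Gene symbols came from a table of identifiers in which 55141 of the 55487 matched, and the unmatched ones took at most 0.0319% of a library's reads. Library totals ran from 23070147 to 33907984 estimated reads. Counts of PCR reads without molecular identifiers are not independent molecules.

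Groups and replicate numbers were taken from the sample titles. The choices of test, lists, named genes and alternatives were made before the data were examined, except where the text says otherwise. The main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3) with TMM factors, its expression filter (minimum count 10, minimum total count 15) and the group as the single term, with Benjamini-Hochberg adjustment over 17339 genes and a threshold of 0.05. Standard errors of single genes were derived from the fold change and the F statistic. Those of list medians were taken over the list's genes, which are not independent, so they can understate the spread between libraries. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on voom log2 CPM, with an estimated correlation and with fry beside it. The 36 lists held 720 symbols, of which 15 were not in the annotation and 664 were tested. Another 4 lists (immunoglobulin constant genes and J chain, cholesterol synthesis and uptake, disease-associated microglia, cytosolic aminoacyl-tRNA synthetases) were chosen after seeing the data. Single values were compared with exact two-sided permutation tests, whose smallest p for 4 against 4 libraries is 0.0286.

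The genes named were Ppp1r17, the 12 genes with the largest increase and the 12 with the largest decrease among those past the threshold with an average log2 CPM of at least 3 and groups that did not overlap (785 genes, predicted genes and pseudogenes left out), and from each list up to 4 measured members with the smallest p. Other genes named were chosen after their values were seen. Some genes these rules select are not reported here.

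Replicates were checked as separate libraries: pairs within a group differed by 7.48 to 41.1 times the counting noise (chi-square per degree of freedom). Data were also simulated with the shfLuc means, the real library sizes and dispersions from the fitted trend (17339 genes, 200 changed). There the test recovered 61.2%, 76.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, and 5.39% of calls were false. Simulated libraries of a group were alike, unlike the real shPpp1r17 libraries, so these rates need not hold for genes that vary within that group.

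Sequence matches were searched in 3' UTRs of at least 50 bases from the GENCODE M21 annotation of GRCm38, available for 14261 of the tested genes (82.3%), with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. For each of 16384 7-mers, the fold changes of genes with and without it were compared and set against 1000 shuffles of the gene labels. In simulated data over these 14261 genes, a planted log2 effect of -0.1 or -0.2 was recovered for 10 of 10 7-mers and an effect of -0.05 for 6 of 10. The annotation's coordinates may differ from those of the authors' build.

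Alternatives were DESeq2 1.42.0, limma voom with and without sample quality weights, RLE factors, library totals, other filters, effective length offsets, limma on log2(TPM + 1) with a pseudocount of 1, robust dispersion, the replicate number as a block, and each library left out. Added after seeing the data were an offset for the trend of each library with gene length and GC content (99.9% of tested genes had a GC value), the fit without the shPpp1r17 libraries 2 and 3, which lie farthest out on the first principal component (32.3% of variance), and the fit without genes holding the sequence match or lacking a searchable 3' UTR.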

Results

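Gene expression was measured by RNA sequencing in the dorsomedial hypothalamus (DMH) of mice, a nucleus involved in feeding, arousal and daily rhythms. The sample names mark the tissue as taken by laser microdissection. A short hairpin RNA against Ppp1r17, an inhibitor of protein phosphatases (group shPpp1r17), was compared with a hairpin against firefly luciferase, which has no mouse target (group shfLuc), with 4 libraries in each group. The libraries held 23070147, 23436873, 23203833 and 25749643 estimated reads in shfLuc 1 to 4, and 25792243, 25637389, 27499926 and 33907984 in shPpp1r17 1 to 4. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

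The targeted gene answered whether the hairpin lowered its transcript. Ppp1r17 (ENSMUSG00000002930; chromosome 6, 56017497 to 56032689 on the plus strand in GRCm38) stood at 160 ± 9.99 CPM (SD, n = 4) in shfLuc, with 147, 161, 161 and 171 CPM in libraries 1 to 4. In shPpp1r17 it stood at 87.7, 2.07, 3.10 and 87.2 CPM in libraries 1 to 4, from 2246, 53, 85 and 2966 reads. These levels were 54.8%, 1.29%, 1.94% and 54.5% of the shfLuc mean. All shPpp1r17 libraries lay below all shfLuc libraries, and the exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 libraries allow. The fitted log2 fold change was -1.83 (SE 0.80) with an adjusted p of 0.197 in edgeR's quasi-likelihood test, so Ppp1r17 did not pass the threshold across all genes. It passed with limma voom (-3.31, adjusted p = 0.0368) and with limma voom and sample quality weights (-3.85, adjusted p = 0.00746). Without the shPpp1r17 libraries 2 and 3, an alternative chosen after seeing the data, the log2 fold change was -0.88 with an adjusted p of 0.00428 in edgeR.

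**Figure D1:**
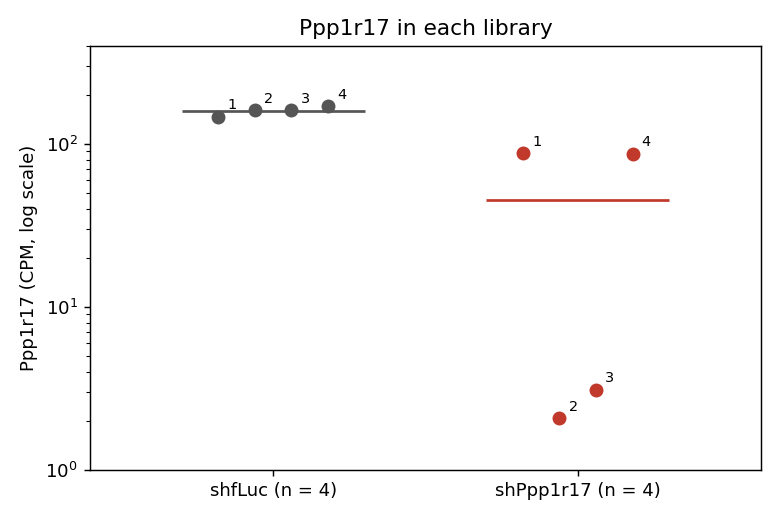
Ppp1r17 in CPM (reads scaled to library size) on a log axis, 1 point per library with its replicate number, and a line at each group mean. The shfLuc libraries sit between 147 and 171 CPM, the shPpp1r17 libraries 1 and 4 at 87.7 and 87.2 CPM, and the shPpp1r17 libraries 2 and 3 at 2.07 and 3.10 CPM.

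Immune, myelin, blood and ribosomal protein genes were among those higher in shPpp1r17, and glutamate and GABA receptor genes were among those lower. Of 17339 genes tested, 1050 passed an adjusted p of 0.05 in edgeR, 588 higher and 462 lower in shPpp1r17. The median log2 fold change was 0.61 among the genes called higher and -0.47 among those called lower, and 109 genes rose and 22 fell by at least 2-fold. The groups did not overlap for 965 of the called genes, and for 13.9% of all tested genes against 2.86% by chance. On log2(TPM + 1) with limma, 797 genes passed and the split turned from 56% higher to 38.8% higher. The count rested on single libraries: edgeR called 0 genes without shfLuc 2 or without shfLuc 3 (3309 and 3146 genes at an unadjusted p under 0.05), where limma voom called 0 and 0 and DESeq2 1140 and 1094. It was 287 without shfLuc 4, 310 without shPpp1r17 2, 196 without shPpp1r17 3, and 37 without both shPpp1r17 2 and 3. All 1050 called genes kept their sign and an unadjusted p under 0.05 with each library left out. They were selected on these same libraries, so this follows largely from the selection and does not show that the calls are stable.

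The largest increases were in immunoglobulin and phagocyte genes. Among the 12 genes with the largest increases were Ighm, the heavy chain of IgM (log2 fold change 3.03, SE 0.64, 30.8 ± 4.17 against 253 ± 298 CPM, SD, n = 4), and Jchain, which links secreted immunoglobulin (4.16, SE 0.92). Ighg2b (6.16), Igkv13-85 (7.57, SE 1.15), the kappa variable segment ENSMUSG00000094335 (7.26, SE 0.96) and Ighv1-22 (5.38, SE 1.16) were at 0 reads in at least 2 shfLuc libraries, so their folds rest on few shfLuc reads. Variable segments of near-identical sequence can share reads, so the identity of single segments is uncertain. Gpnmb, a lysosomal glycoprotein of phagocytes, rose from 1.21 ± 0.69 to 23.6 ± 25.6 CPM (SD, n = 4). Lyz2, the macrophage lysozyme, rose from 14.4 ± 6.21 to 76.9 ± 54.0 CPM, and Gfap, the intermediate filament of astrocytes, from 57.8 ± 19.5 to 204 ± 110 CPM. The folds of Gpnmb and Ighm rest mostly on the shPpp1r17 libraries 2 and 3, with 104, 1455, 841 and 96 reads of Gpnmb and 1535, 17616, 5504 and 2094 of Ighm in shPpp1r17 1 to 4. Fcgr2b (1.58), Cd68 (1.42) and Glipr1 (1.30) completed the 12 on the log2 scale. Immunoglobulin transcripts took 0.0268% ± 0.0409 of reads in shfLuc and 0.248% ± 0.132 in shPpp1r17 (SD, n = 4; exact permutation p = 0.0571).

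**Figure D2:**
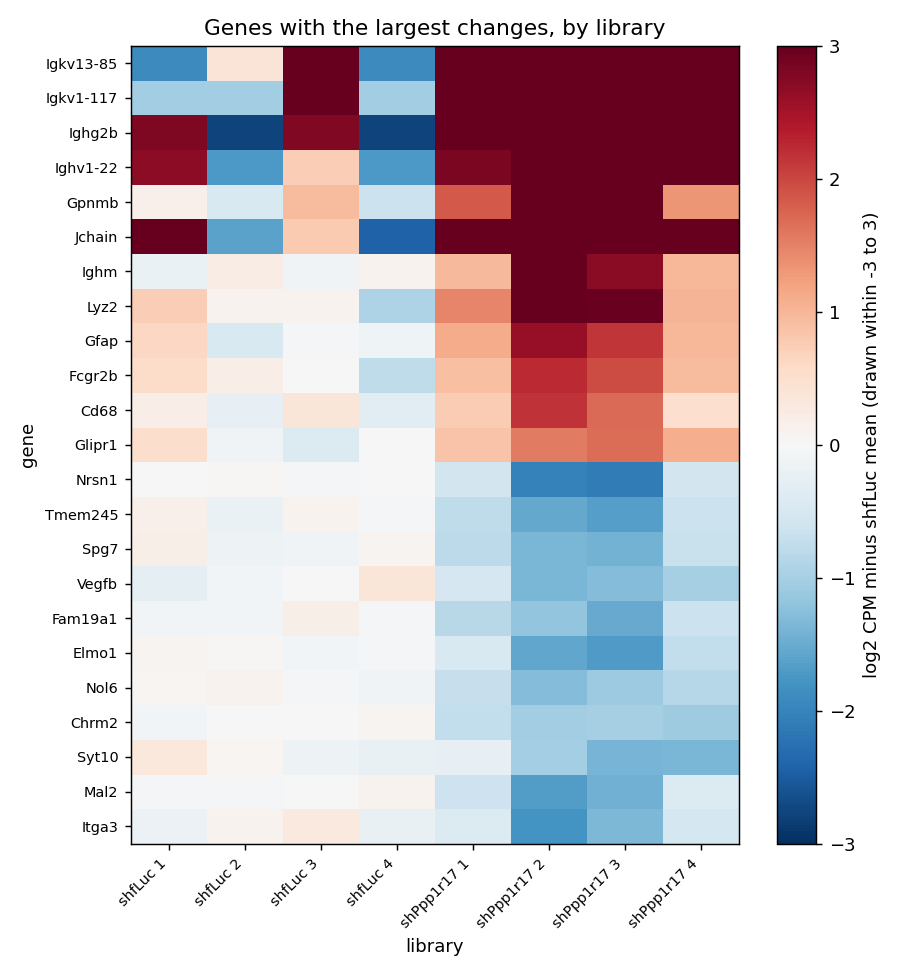
Genes with the largest increases (top 12 lines) and decreases (below) in each library (columns), as log2 CPM minus the shfLuc mean, drawn within -3 to 3. For Nrsn1 and Gfap the shPpp1r17 libraries 2 and 3 lie farther from the shfLuc mean than the shPpp1r17 libraries 1 and 4.

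Microglial, complement and interferon genes were among those that rose. In the list of microglia and macrophages 9 of 17 measured genes rose and 0 fell (12 adjusted over the list alone), among them the complement genes C1qa (0.97, SE 0.17) and C1qb, with a camera adjusted p of 7.06e-07 (adjusted p = 0.320 with an estimated correlation). In antigen presentation and complement 7 of 19 rose (14 adjusted over the list alone), with C3 at 1.84 (SE 0.38) and C1qc at 0.89 (SE 0.20), and a camera adjusted p of 8.94e-08 (adjusted p = 0.320 with an estimated correlation). In the type I interferon response 4 of 22 rose (9 adjusted over the list alone), Rtp4 (0.87), Ifitm3 (0.93), Usp18 (1.38) and Isg15 (1.38), with a camera adjusted p of 1.24e-05 (adjusted p = 0.363 with an estimated correlation). In reactive gliosis 3 of 18 rose (8 adjusted over the list alone), Gfap, C3 and the intermediate filament Vim (1.20, SE 0.22), with a camera adjusted p of 0.000577 (adjusted p = 0.320 with an estimated correlation). These 4 lists did not pass with fry (adjusted p = 0.0762, 0.0871, 0.136 and 0.0737). Their medians overlapped between groups. Relative to the shfLuc mean they were 0.40, 0.75, 0.46 and 0.26 in shfLuc 1, and 0.37, 0.41, 0.24 and 0.16 in shPpp1r17 4.

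Blood and myelin markers were also among the genes that rose. In blood cells 5 of 8 measured genes rose (8 adjusted over the list alone): the hemoglobin genes Hbb-bs (0.99, SE 0.19), Hba-a1 (0.93), Hba-a2 (0.94) and Hbb-bt (1.25), and Alas2 (1.17), an enzyme of heme synthesis, with a camera adjusted p of 2.70e-07 (adjusted p = 0.320 with an estimated correlation). Near-identical hemoglobin copies can share reads. Hemoglobin transcripts took 0.0434% ± 0.0104 of reads in shfLuc and 0.0852% ± 0.0255 in shPpp1r17 (SD, n = 4; exact permutation p = 0.0286). In oligodendrocytes 5 of 15 rose (9 adjusted over the list alone), with the tight junction gene Cldn11 at 1.02 (SE 0.20), Mobp at 0.79, Enpp6 at 1.37 and Ermn at 0.60, and a camera adjusted p of 1.34e-06 (adjusted p = 0.329 with an estimated correlation, and 0.103 with fry). The list medians relative to the shfLuc mean were 0.23, 0.88, 0.84 and 0.13 in shPpp1r17 1 to 4. Most of the rise was in libraries 2 and 3. In pericytes, smooth muscle and vascular leptomeningeal cells 1 of 14 rose, Dcn (0.89, SE 0.17), with a camera adjusted p of 0.0129 (adjusted p = 0.405 with an estimated correlation, 0.167 with fry and 0.178 without the shPpp1r17 libraries 2 and 3). In endothelial cells 1 of 12 rose, Ly6c1 (0.84, SE 0.17), with a camera adjusted p of 0.216. In ependymal cells, tanycytes and choroid plexus 3 of 12 rose and 1 fell (5 and 1 adjusted over the list alone), Crym at 2.11 (SE 0.46) and Rarres2 at 0.64 among the first and Clic6 at -0.80 (SE 0.18), with a camera adjusted p of 0.0456 (adjusted p = 0.405 with an estimated correlation, and 0.187 with fry). This call was also lost without shfLuc 1 (0.107), shfLuc 3 (0.176), shfLuc 4 (0.125), shPpp1r17 1 (0.116) or shPpp1r17 2 (0.143), without the shPpp1r17 libraries 2 and 3 (0.0640) and over the searched genes without the motif described below (0.0968).

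Ribosomal protein genes rose almost as a whole. Of 40 measured cytosolic ribosomal protein genes 38 rose (40 adjusted over the list alone), with a median log2 fold change of 0.61, Rps19 at 0.88 (SE 0.13), Rps7 at 0.81 (SE 0.12), Rpl4 at 0.71 (SE 0.10) and Rps3 at 0.78 (SE 0.12), and a camera adjusted p of 3.11e-36 (adjusted p = 0.296 with an estimated correlation). They took 2.66% ± 0.232 of reads in shfLuc and 4.13% ± 0.695 in shPpp1r17 (SD, n = 4; exact permutation p = 0.0286). With the length and GC trend of each library removed, an alternative chosen after seeing the data, the median was 0.42 and 29 rose. Immediate early genes, which respond to neuronal activity and stress, rose in 5 of 19 (8 adjusted over the list alone), with Fos at 1.04 (SE 0.20), Egr1 at 0.83 (SE 0.21), Jun at 0.68 (SE 0.17) and Btg2 at 0.49 (SE 0.10), and a camera adjusted p of 0.00731 (adjusted p = 0.258 with an estimated correlation). In the unfolded protein response and heat shock list 2 of 22 rose and 1 fell (4 and 2 adjusted over the list alone), Atf4 (0.41), Xbp1 (0.26) and Pdia3 (-0.53), with a camera adjusted p of 0.0229 (adjusted p = 0.332 with an estimated correlation, and 0.0840 with fry). This call was also lost on log2(TPM + 1) (0.0798), without shfLuc 3 (0.0521), shPpp1r17 1 (0.0679) or shPpp1r17 2 (0.0886), and without the shPpp1r17 libraries 2 and 3 (0.178). In nuclear oxidative phosphorylation 2 of 35 rose (3 adjusted over the list alone), Cox4i1 (0.32) and Cox7c (0.29), with a camera adjusted p of 0.0116 (adjusted p = 0.405 with an estimated correlation, and 0.0871 with fry). This call was also lost on log2(TPM + 1) (0.205) and without shfLuc 3 (0.0521), and the direction turned down with the length and GC trend removed (camera adjusted p = 0.107).

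A part of the mitochondrially encoded transcripts fell: 3 of 15 fell, 0 rose and 12 did not pass (8 fell adjusted over the list alone), mt-Rnr2 (-0.54, SE 0.10), mt-Nd4l (-0.56, SE 0.10) and mt-Nd2 (-0.50, SE 0.13), with a camera adjusted p of 2.91e-06 (adjusted p = 0.320 with an estimated correlation, and 0.0871 with fry). The list medians relative to the shfLuc mean were -0.12, -0.34, -0.38 and 0.00866 in shPpp1r17 1 to 4. Mitochondrial transcripts took 6.42% ± 0.514 of reads in shfLuc and 5.35% ± 0.625 in shPpp1r17 (SD, n = 4; exact permutation p = 0.0571), with shPpp1r17 4 (6.016%) above shfLuc 3 (6.001%).

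The largest decreases were in genes of varied function. Nrsn1, a neuronal vesicle protein, fell from 372 ± 6.60 to 172 ± 96.0 CPM (SD, n = 4; log2 fold change -1.11, SE 0.30). Chrm2, a muscarinic acetylcholine receptor, fell from 24.8 ± 1.23 to 12.8 ± 1.42 CPM (-0.96, SE 0.11), and Nol6, a nucleolar protein, from 40.0 ± 2.78 to 20.4 ± 3.85 CPM (-0.97, SE 0.12). Others with the largest decreases were Tmem245 (-1.09), Spg7 (-1.04), Vegfb (-1.02), Fam19a1 (-1.02), Elmo1 (-1.02), Syt10 (-0.95), Mal2 (-0.94) and Itga3 (-0.92). All of these but Syt10 held in the 3' UTR a 7-base or 8-base match to the motif CTCTGATA. So did 240 of 436 searched genes called lower (55.1%), against 18.7% of all 14261 genes searched. The motif extends the 7-mer that went with the lowest fold changes in these same libraries, so these shares are not independent evidence for it. The odds ratio for a match among genes called lower was 5.74, and 4.31 with 3' UTR length taken into account. The motif lies at 2 places in the Ppp1r17 mRNA, at chromosome 6, 56026533 to 56026540 (exon 4, coding sequence) and 56032367 to 56032374 (exon 5, 3' UTR) in GRCm38. Without the genes holding such a match or lacking a searchable 3' UTR, an alternative chosen after seeing the data, 433 genes were higher and 184 lower in edgeR.

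A part of the receptor and ion channel genes of neurons fell. Of 24 glutamate receptor genes 5 fell and 0 rose (10 fell adjusted over the list alone), with Gria3 at -0.42 (SE 0.08), Grin2a at -0.58 (SE 0.13) and Grm5 at -0.49 (SE 0.12), and a camera adjusted p of 5.21e-07 (adjusted p = 0.258 with an estimated correlation, and 9.34e-05 over the searched genes without the motif). Of 20 GABA and glycine receptor genes 5 fell (8 fell and 1 rose adjusted over the list alone), with Gabrb2 at -0.87 (SE 0.11), Gabbr2 at -0.61 (SE 0.15) and Gabrg3 at -0.32 (SE 0.09), and a camera adjusted p of 0.000959 (adjusted p = 0.320 with an estimated correlation). These 3 genes held a match to the motif, and the list's camera adjusted p was 0.0784 over the searched genes without it. The GABA and glycine receptor medians relative to the shfLuc mean were -0.08, -0.32, -0.29 and -0.07 in shPpp1r17 1 to 4, lowest in libraries 2 and 3. Of 31 voltage-gated ion channel genes 3 fell (5 adjusted over the list alone), Kcnd2 (-0.30), Cacna2d1 (-0.42) and Scn9a (-0.34), with a camera adjusted p of 0.00140 (adjusted p = 0.258 with an estimated correlation, and 0.221 with the length and GC trend removed). Of 30 genes of postsynaptic scaffold and adhesion 4 fell (5 adjusted over the list alone), Cadm1 (-0.51), Gphn (-0.60), Camk2a (-0.69) and Cntnap2 (-0.50), with a camera adjusted p of 0.0180 (adjusted p = 0.320 with an estimated correlation, 0.117 over the searched genes without the motif and 0.382 with the trend removed). In presynaptic vesicle release 3 of 30 fell, Pclo (-0.40), Syt1 (-0.37) and Rph3a (-0.39), and Bsn rose (0.53) (5 and 2 adjusted over the list alone), with a camera adjusted p of 0.127 and a fry adjusted p of 0.0381, direction down.

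Markers of neurons as a class were mixed. Of 16 neuronal genes 3 fell, Syt1, Nefl (-0.39) and Eno2 (-0.43), and 1 rose, Tubb3 (0.38), with a median of -0.06, a camera adjusted p of 0.589 and a fry adjusted p of 0.0308, direction down. In glutamatergic neurons 2 of 8 fell (4 adjusted over the list alone), the vesicular transporter Slc17a6 (-0.33, SE 0.07) and Grin2a, with a camera adjusted p of 0.0116 (adjusted p = 0.320 with an estimated correlation, 0.0737 with fry, 0.157 over the searched genes without the motif and 0.0985 without the shPpp1r17 libraries 2 and 3). In GABAergic neurons 0 of 11 passed, with Gad2 at -0.21 (SE 0.06, adjusted p = 0.0683 in edgeR) and a camera adjusted p of 0.494. In astrocytes 2 of 15 rose, Gfap and S100b (0.29), and 3 fell, Slc4a4 (-0.32), Agt (-0.61) and Slc1a3 (-0.46) (2 and 5 adjusted over the list alone), with a camera adjusted p of 0.214. In oligodendrocyte precursors 1 of 10 fell, Lhfpl3 (-0.34) (1 fell and 1 rose adjusted over the list alone), with a camera adjusted p of 0.589.

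**Figure D3:**
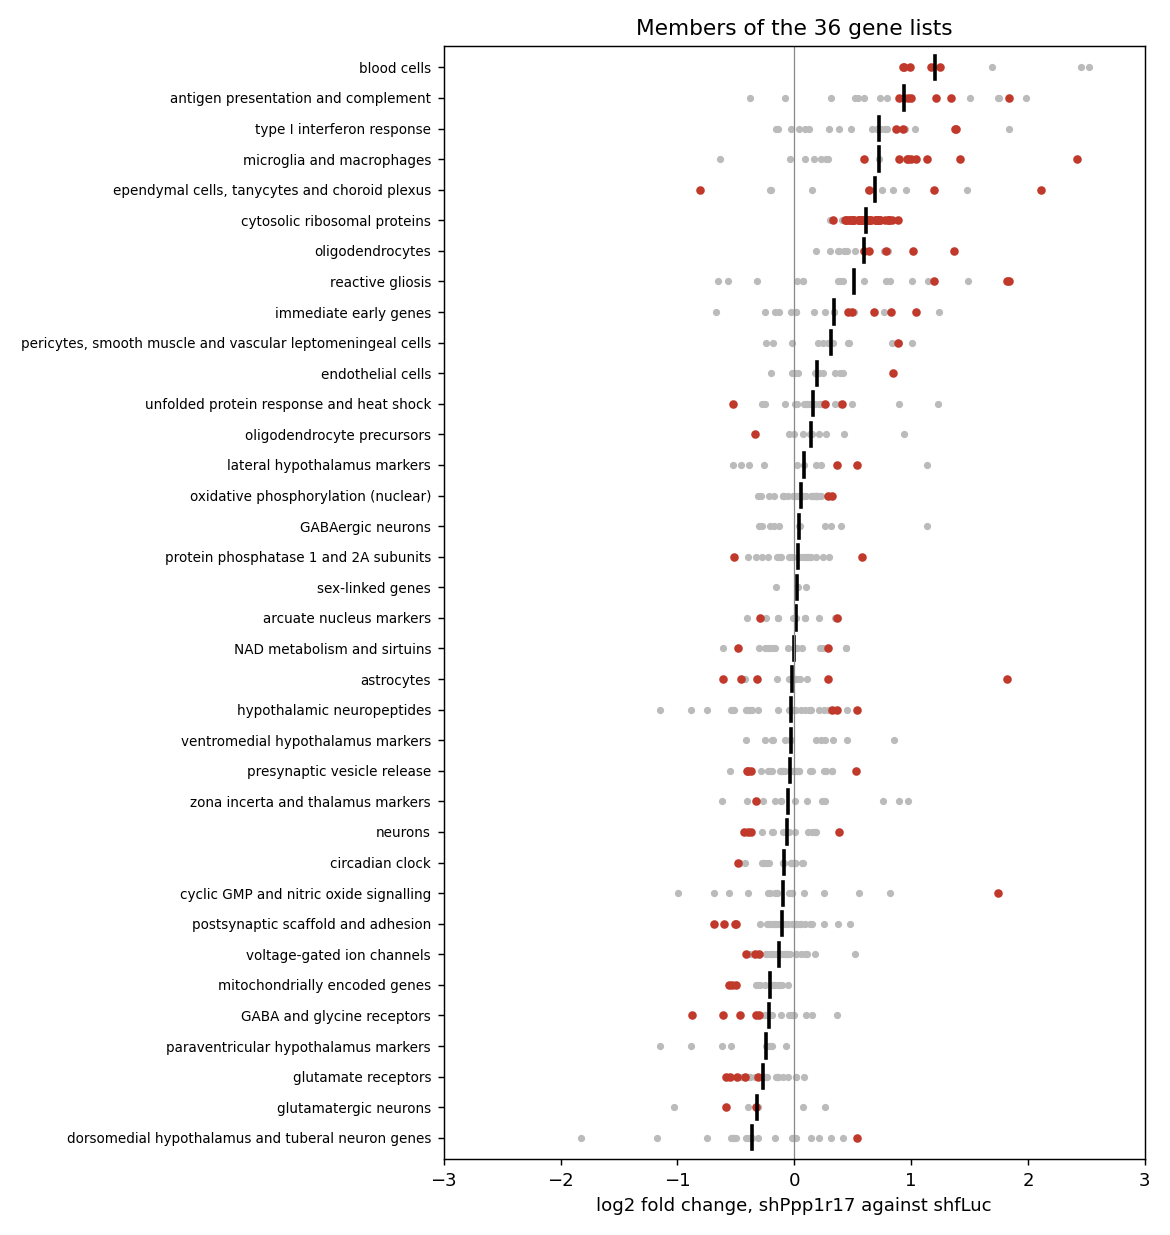
Log2 fold change of each measured member of the 36 gene lists, shPpp1r17 against shfLuc, with red points for members with an adjusted p under 0.05 in edgeR, grey points for the others, and a black bar at each list's median. The ribosomal protein list has a median of 0.61 with 38 red points, and the glutamate receptor list a median of -0.27 with 5.

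Region markers gave a mixed picture. Among the dorsomedial and tuberal genes 1 of 23 rose, Nts (0.54, SE 0.09), and Ppp1r17 belongs to this list, with Brs3 at -1.18 (SE 0.39, adjusted p = 0.0910 in edgeR) and a median of -0.36. Its camera adjusted p was 0.0229 (adjusted p = 0.484 with an estimated correlation, and 0.267 with fry). This call was also lost on log2(TPM + 1) (0.0769), over the searched genes without the motif (0.151), without shPpp1r17 2 (0.109), without shPpp1r17 3 (0.0692) and without both (0.336). Paraventricular markers had 0 of 9 past the threshold and all 9 below 0, with a camera adjusted p of 0.00919 (adjusted p = 0.258 with an estimated correlation). In arcuate markers Cartpt rose (0.37, SE 0.08) and Prlr, the prolactin receptor, fell (-0.30, SE 0.07), with a camera adjusted p of 0.984. In lateral hypothalamus markers 2 of 11 rose, Nts and Cartpt, with a camera adjusted p of 0.432. In zona incerta and thalamus markers 1 of 14 fell, Slc17a6, and in ventromedial markers 0 of 13 passed, with a camera adjusted p of 0.984 for each. Of 32 hypothalamic neuropeptide genes 3 rose, Nts, Cartpt and Nucb2 (0.32) (3 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 0.784.

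Signalling and metabolic lists changed in few members. In the circadian clock 1 of 21 fell (3 adjusted over the list alone), Rorb (-0.48, SE 0.12), with a camera adjusted p of 0.0274 (adjusted p = 0.405 with an estimated correlation, 0.139 with fry, 0.163 with the length and GC trend removed, 0.243 over the searched genes without the motif and 0.407 without the shPpp1r17 libraries 2 and 3). This call was also lost without shfLuc 4 (0.0787), shPpp1r17 2 (0.0723) or shPpp1r17 3 (0.0815). Among the protein phosphatase subunits, the family Ppp1r17 acts on, Ppp2r1b rose (0.58, SE 0.14) and Ppp1r10 fell (-0.51, SE 0.12) out of 24 (3 and 2 adjusted over the list alone), with a camera adjusted p of 0.911. In cyclic GMP and nitric oxide signalling 1 of 18 rose, Nppa (1.74, SE 0.45) (1 rose and 3 fell adjusted over the list alone), with a camera adjusted p of 0.192. In NAD metabolism and sirtuins Nampt rose (0.29, SE 0.07) and Cd38 fell (-0.49, SE 0.12) out of 19 (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.753. The 4 measured sex-linked genes did not pass, with a camera adjusted p of 0.950. Across the 36 lists 21 passed with the preset correlation, 12 higher and 9 lower. With an estimated correlation 0 passed (5 at an unadjusted p under 0.05, lowest adjusted p 0.258), and fry, which tests whether a list moves on balance in a single direction, passed 10, of which neurons and presynaptic vesicle release had not passed camera. The others passed both, with fry adjusted p of 0.0305 for ribosomal proteins, 0.0431 for blood cells and 0.0129 for immediate early genes, all higher. Those lower were voltage-gated ion channels (0.00932), glutamate receptors (0.0129), paraventricular markers (0.0129), postsynaptic scaffold and adhesion (0.0308) and GABA and glycine receptors (0.0407).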

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

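The check of single libraries that follows was set before the data were seen, but part of the genes it covers were named from the results. A library was marked where its gap to the nearest other library of its group took up most of the group's range. Among 318 groups of 4 libraries checked, 18 were marked and 15.9 would be by chance, so these are about as many as chance gives. The shfLuc library 4 had 25.75 M reads (others 23.07 to 23.44 M) and 22764 genes detected (others 22988 to 23029), and Prlr at 6.60 log2 CPM. The shfLuc library 1 had 0.0880% immunoglobulin reads (others 0.00337% to 0.0104%), C1qa at 4.33, Usp18 at 2.498, Rph3a at 7.01 and Cadm1 at 8.28 log2 CPM. The shfLuc library 3 had ENSMUSG00000094335 at 0.44 log2 CPM (others at 0 reads), Slc4a4 at 7.07, Ermn at 4.36, Jun at 3.26 and Gucy1a2 at 2.14 log2 CPM. The shfLuc library 2 had Pclo at 7.47 log2 CPM. In shPpp1r17, library 1 had Chrm2 at 3.90 and Grin2a at 4.55, library 2 had Rarres2 at 5.55 and library 3 had Slc4a4 at 6.76 log2 CPM.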

How the results depend on the processing

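The alternatives with the length and GC trend removed, without the shPpp1r17 libraries 2 and 3 and over the searched genes without the motif were chosen after seeing the data. Genes past the threshold numbered 1050, but 1874 with DESeq2 (1038 of the called genes shared), 1763 with quality-weighted limma voom (1041 shared), 37 without the shPpp1r17 libraries 2 and 3 (32 shared) and 617 over the searched genes without the motif, which leaves out motif-holding genes and genes lacking a searchable 3' UTR. Leaving out each library gave 0 to 1548 genes in edgeR, 0 to 1671 in limma voom and 960 to 2214 in DESeq2. The lowest adjusted p was 0.0505 without shfLuc 2 and 0.0549 without shfLuc 3, and the cause of the lost calls was not tested. The other alternatives gave 705 to 1445 genes. For Ppp1r17 the log2 fold change passed the threshold at -3.85 with quality weights, -3.31 with limma voom and -0.88 without the shPpp1r17 libraries 2 and 3 (the cause was not tested), with adjusted p from 0.00428 to 0.422 over 21 alternatives and -2.37 to -1.43 with each library left out. Gene lists past the threshold numbered 21 (12 higher and 9 lower), but 0 with an estimated correlation and 10 with fry, and 17 to 22 with each library left out. Over the searched genes without the motif 14 of 35 lists passed, 11 higher and 3 lower. Without the shPpp1r17 libraries 2 and 3 the lists past the threshold were 16, with 9 higher and 7 lower. Camera on voom is the main list test, and the DESeq2, unweighted voom and robust dispersion alternatives were not run for lists.

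The same-numbered libraries correlated at -0.0116 to 0.116, so the numbers do not pair them. The replicate block gave 705 genes, 21 lists and a Ppp1r17 log2 fold change of -3.01, not past the threshold. Of the values of the 151 named genes under the alternatives chosen before the data were seen, 2216 kept their direction and side of the threshold, 535 lost the threshold, 110 gained it and 6 turned sign. Eif2s3y turned to -0.0807 with the effective length offset and -0.17 on log2(TPM + 1). With single libraries left out Eif2s3y ranged from -0.00166 to 0.0527 and Kdm5d from -0.0613 to 0.0901. Without the shPpp1r17 libraries 2 and 3 the log2 fold change was 0.0337 for Sst, -0.0593 for Bmp4, -0.0406 for Pecam1, -0.0270 for Slco1a4 and -0.19 for Kdm5d. The turned values did not pass the threshold, and the cause was not tested. At this depth Ppp1r17 in the shPpp1r17 libraries 2 and 3 rests on 53 and 85 reads.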

Other observations

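The 4 lists of the opening paragraphs and the tests on the share of neurons, on blood and on control tissue were chosen after the results they bear on were seen.

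Genes of cholesterol synthesis and uptake rose together in shPpp1r17: 13 of 25 measured genes rose and 0 fell, with Msmo1 at 0.79 (SE 0.12), Fdft1 at 0.84 (SE 0.14) and Sqle at 0.77 (SE 0.13) on the log2 scale. The list was chosen after these values were seen, so its camera adjusted p of 5.61e-13 is not independent evidence (adjusted p = 0.128 with an estimated correlation). The list medians relative to the shfLuc mean were 0.25, 0.84, 0.76 and 0.32 in shPpp1r17 1 to 4, highest in libraries 2 and 3.

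Genes known from phagocytic microglia in diseased tissue rose in 10 of 17 measured members, with Clec7a at 2.58 (SE 0.40), Lgals3 at 2.79 (SE 0.46) and Cst7 at 2.95 (SE 0.74) (camera adjusted p of 5.54e-07, and adjusted p = 0.128 with an estimated correlation). Of 9 immunoglobulin constant genes and Jchain 5 rose, with Iglc2 at 4.43 (SE 0.92) (camera adjusted p of 4.37e-06, and adjusted p = 0.128 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases 2 rose, Sars (0.41) and Nars (0.41), and 1 fell, Wars (-0.84, SE 0.13), with a camera adjusted p of 0.0714. These lists were also chosen after the values were seen.

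For the genes lower in shPpp1r17, a candidate explanation is silencing through the seed of the hairpin. Of 16384 7-mers, CTCTGAT in 3' UTRs went with the lowest fold changes (z of -12.89, against -5.16 as the lowest of 1000 shuffles). It occurs 3 times in the Ppp1r17 mRNA, where 9.39% of all 7-mers occur. The mean difference grew from -0.09 for 7mer-A1 to -0.11 for 7mer-m8 and -0.20 for 8mer sites. For genes with 8mer or 7mer-m8 sites the difference per library was -0.08, -0.20, -0.18 and -0.06 in shPpp1r17 1 to 4, against -0.01 to 0.02 in shfLuc. The 7-mer was picked on these same libraries, so the differences per library are not independent evidence for it. A length and GC trend as the whole cause is argued against, since 68.0% of the genes called lower stayed called with the trend removed. A smaller share of neurons stays open. The neuronal list had a median of -0.0587 (SE 0.0756, over its genes) against -0.47 for the genes called lower. That comparison cannot decide, because the genes called lower were selected for being lower. Fry passed the neuronal list as lower (adjusted p = 0.0308), but camera did not (adjusted p = 0.589), and 7 of its 16 genes lay above 0. Its medians relative to the shfLuc mean were small, at -0.01, -0.02, -0.08 and -0.01 in shPpp1r17 1 to 4. Of its genes called lower, Nefl and Eno2 held a 7-base or 8-base match to the motif, and Syt1 only the shorter match. The hairpin sequence was not analysed here, and a microRNA of the tissue with the same seed stays open. Of the searched genes called lower, 196 held no such site. Among these, 72 held the shorter match TCTGAT in the 3' UTR, as did 61 genes called higher. With no 3' UTR match, an 8mer site in the coding sequence went with 12 genes called lower and 0 called higher. The counts were 23 and 24 for 7mer-m8 and 9 and 7 for 7mer-A1 sites there. Near-equal counts do not show that a shift is absent, since genes with no 3' UTR match split into 124 called lower and 393 called higher. The mean difference was -0.08 (confidence interval -0.11 to -0.06) for 7mer-m8 sites in the coding sequence. It was -0.016 (-0.029 to -0.0028) for the shorter match in the 3' UTR. For 7mer-A1 sites in the coding sequence the interval included 0 (-0.018, -0.06 to 0.03). An effect of lower Ppp1r17 itself stays open for the genes with and without a site, and was not tested.

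For the genes higher in shPpp1r17, blood left in the tissue as the whole cause is argued against by the oligodendrocyte list. Blood cells do not bring its genes. The list had a median of 0.60 (SE 0.10, over its genes) and lay higher in every shPpp1r17 library than in every shfLuc library. Blood stays open for the blood and immune genes: immunoglobulin constant genes and Jchain had a median log2 fold change of 3.58 against 1.25 for the highest hemoglobin gene, but Jchain, Ighm and Ighg2b are themselves among the largest increases, and the list median relative to the shfLuc mean was 3.25 in shfLuc 1 and 2.96 in shPpp1r17 4. A length and GC trend as the whole cause of the ribosomal protein increase is argued against. With the trend removed the list's median was 0.42 (SE 0.03, over its genes), against 0.61 before. Part of its genes still rose past the threshold. These genes move together (estimated correlation 0.856), so the SE understates the spread between libraries. More microglia, infiltrating immune cells, a response to the hairpin or its delivery and an effect of Ppp1r17 stay open and may act together.

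For the unequal Ppp1r17 levels, purely control tissue in the shPpp1r17 libraries 1 and 4 is argued against, since the lowest shfLuc library lay 0.74 above the higher of the 2 on the log2 scale (SD of shfLuc 0.09). Uneven capture of the dorsomedial and tuberal area as the whole cause is argued against by the other genes of that list. Their medians were -0.45 (SE 0.24, over genes) and -0.37 (SE 0.19) in the shPpp1r17 libraries 2 and 3, above the bound of -1 set beforehand. They were -0.0934 and 0.10 in libraries 1 and 4. The list does not speak for the nucleus alone, since Trh, Nts, Pdyn and Ghrh also belong to the paraventricular, lateral or arcuate lists. A partial difference in capture, or uneven capture of the nucleus within that area, stays open. In libraries 2 and 3 Nmu, whose 3' UTR holds no match to the motif, was at -2.55 and -1.35. Prdm13 was at -1.83 and -0.80, Cck at -1.15 and -1.19, Grp at -0.98 and -1.07, and Trh at -0.76 and -1.07. Only Ghsr, Nts and Gpr50 lay above the shfLuc mean in both libraries. Brs3, at -2.61 in library 2, holds an 8mer site. The mean difference for genes with 8mer sites was -0.30 in that library, so the level of Brs3 may reflect the site, capture or both. Unequal delivery of the hairpin or a mixture of targeted and untargeted tissue may remain and was not tested.

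Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes past the threshold, the real split with 1050, and the highest other gave 26, so an accidental division of the libraries is argued against. This is the smallest share that 35 splits allow. Every other split mixes the groups, so a real difference adds spread there and the gap from 1050 to 26 does not measure its strength. The splits cannot tell the hairpin from another difference that goes with the groups.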
